A study of Arabidopsis thaliana with 8 samples.

How the data were processed

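Messenger RNA of whole rosettes of the *Arabidopsis thaliana* pgm mutant in the Col-0 background was measured on 8 one-colour Affymetrix arrays, each hybridised with biotin-labelled cRNA. The mutant lacks plastidial phosphoglucomutase and makes almost no starch in its leaves. Per the labels' protocols, 5 harvests of 3 rosettes were frozen inside the growth chamber for a sample, the material of 15 rosettes was ground, TriZol was used on 250 mg of this powder, and labelling began from about 10 µg of RNA. The arrays carry the hours 00h, 04h, 08h, 12h, 16h and 20h. The hours 00h and 12h have 2 arrays each, lettered A and B, and the other 4 hours have 1 array each, lettered A. The series' design text speaks of 8 times, while the labels give 6 hours over 8 arrays. The labels used here give neither the hours of light and dark nor whether A and B came from separate plants, so p-values measure only the spread between these arrays, which may be technical. A wild type is not analysed here.

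The deposited table holds 1 intensity value per probe set and array on a linear scale. The submitters' processing notes name MAS5, Affymetrix's summary of perfect-match and mismatch probes, with no version. The mean of the deposited intensities after trimming 2% at each end was 100 on every array, so the values are scaled to a common mean. A scaling of this kind removes any difference in total mRNA between hours and moves all probe sets of an array together. Every array had values of 0, between 5 and 52 of 22810 probe sets. The median intensity ran from 29.9 at 00h B to 37.6 at 04h.

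From the deposited intensities, log2(value + 16) was computed. The 64 control probe sets were left out. Of the remaining 22746 probe sets, the 40% with the lowest mean were left out before any fit, which left 13647. A log2 change on this scale understates the change of dim probe sets. Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The 24 h rhythm was the F test of the cosine and sine of the hour over all 8 arrays, with 5 residual degrees of freedom, and gave an amplitude (from mid-level to peak), a peak hour and their standard errors. The contrast 12h minus 00h and the 6 steps between neighbouring hours came from 1 fit with the hour as a factor, with 2 residual degrees of freedom from the paired arrays of 00h and 12h. An hour with 1 array was assumed to vary like these. On simulated data with 13647 probe sets, the 12h vs 00h test recovered 68% of changes of 1 log2 unit and 100% of changes of 2 units, with 20 false calls. The rhythm test recovered 43% of amplitudes of 0.5 and 99% of amplitudes of 1, with 6 false calls. The simulated noise was normal, independent between probe sets and free of an array batch, and few probe sets were altered. These rates may therefore not hold for the data.

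Probe sets were named through the platform's gene table. It gives 1 gene for 13513 of the probe sets, several for 503 and none for 8730, and only probe sets with 1 gene are named here. Symbols were brought up to date through the gene identifiers of the RefSeq table of assembly TAIR10.1, from which no coordinates are used. Gene names follow the tables, and a locus stands where no symbol is given. The 20 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Of the 254 members of these lists 41 have a named probe set and 40 were tested. Another 31 lists were written afterwards from gene names and loci alone, before any test was run. Each gene entered a list with its brightest probe set. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over 56 pairs of list and contrast for the fixed lists and over 210 for the added ones. With the correlation estimated from the data, none of the calls held in either family, and the lowest adjusted p was 0.821 for the fixed lists and 0.58 for the added lists. This setting tests on the 2 residual degrees of freedom of the fit, so it cannot show that correlation within a list undoes a call. For 107 cytosolic ribosomal protein genes at 12h vs 00h the estimated correlation was -0.00654, below the preset. Their camera p still went from 7.98e-17 to 0.00693. Several other lists that passed had estimates far above the preset, such as 0.984 for starch synthesis, 0.494 for autophagy and 0.406 for flavonoid modification. That of the fixed sugar starvation list was 0.0323, and some lists that passed had estimates below 0. For lists with a high estimate the camera p at the preset may be too small. With fry, 0 fixed and 5 added pairs passed.

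The text names the 12 highest and 12 lowest changes for 12h vs 00h among probe sets past the threshold whose arrays did not overlap. It also names the 12 largest amplitudes and the clock list members, the 3 highest and 3 lowest changes per step, and up to 4 members per list by the size of the test statistic. Other genes are said to be chosen after their values were seen.

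Hybridisation controls split the arrays. The geometric mean of 9 spiked control probe sets was 390.9 at 00h A and 401.1 at 12h A, against 109.3 to 134.1 on the other 6 arrays, a ratio of 3.23. The brightest probe sets also reached higher there, with a 99.9th percentile of 6417 and 6290, against 3288 to 4494. These 2 arrays and the other 6 were treated as 2 array batches, a choice made after seeing the data. The labels give no batch. The array's own controls of RNA quality, 3' over 5' intensity, ran from 2.29 to 3.19 for actin and from 0.924 to 1.18 for GAPDH. For ubiquitin they were 2.98 at 00h A, 1.63 at 00h B, 2.39 at 12h A and 2.05 at 12h B, and 1.75 to 1.88 at the other hours. The 25S rRNA control was 2995.5 at 00h A against 65.8 to 869.3 elsewhere. The 00h A and B arrays gave equal values for 312 probe sets and the 12h arrays for 224, so no array was a copy. The alternatives tried were pseudocounts of 1 and 64, no filter, a filter at 60%, quantile normalization, median scaling, no intensity trend, the replicate letter as a block, each array left out in turn, other curves for the rhythm, only the 4 arrays of 00h and 12h, other set tests and, added after seeing the data, the array batch.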

Results

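Expression over the day was followed in rosettes of the pgm mutant at 6 hours, with 2 arrays at 00h, 2 at 12h and 1 at each of 04h, 08h, 16h and 20h. The design asks how transcript levels in this mutant change over the day. Values are deposited intensities, given as mean ± SD where an hour has 2 arrays and as a single value elsewhere. PGM1 (AT5G51820), the gene of the missing enzyme, has no named probe set among those used here, so its level is not analysed here. On 13647 tested probe sets log2 values correlated at 0.917 or more among the 04h, 08h and 12h arrays and at 0.9116 or more among the 16h, 20h and 00h arrays. Between these 2 groups of arrays the correlation ran from 0.7085 to 0.865.

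The largest rises from 00h to 12h included 2 *COR15* genes, 3 genes of flavonoid metabolism and *BCAT4*. *COR15A*, which encodes a chloroplast protein induced by cold, went from 29.95 ± 11.4 to 1952 ± 707 (SD, n = 2 arrays each), a log2 change of 5.40 ± 0.284 (SE; limma adjusted p = 1.16e-06). *COR15B* rose by 4.50 ± 0.218 and *AT4G30650* by 5.10 ± 0.236. *AT1G06000*, a flavonol rhamnosyltransferase gene, rose by 4.41 ± 0.266, *AT4G14090*, an anthocyanin glucosyltransferase gene, by 3.77 ± 0.267 and *CHIL*, a chalcone isomerase-like gene, by 3.72 ± 0.226. The 00h signals of *AT4G14090* and *CHIL*, 4.75 and 2.2, lie near 0, and the sizes ran from 2.254 to 5.866 and from 2.124 to 6.151 with other pseudocounts. That of *AT1G06000* was also low, 9.6 ± 8.49, and its size ran from 2.973 to 5.876 across the alternatives. *BCAT4*, an aminotransferase gene of methionine-derived glucosinolate synthesis, rose from 115 ± 22.2 to 1919 ± 270. The other genes among the 12 highest were *TBL26*, *AT1G07050*, *AT1G73600* (a phosphoethanolamine methyltransferase gene), *AT4G34950* and *AT1G68600*, with log2 changes between 3.79 and 4.78 (*AT1G07050* 2.835 with a pseudocount of 64).

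The opposite change was as large. *AT2G20670* fell from 1338 ± 579 at 00h to 2.05 ± 0.0707 at 12h (SD, n = 2 arrays each), a log2 change of -6.16 ± 0.285 (SE; limma adjusted p = 6.34e-07). The 12h signal lies near 0, and the size ran from -8.708 to -4.343 with other pseudocounts. *AT3G15450* had a log2 change of -5.69 ± 0.39. *AKINBETA1*, a subunit gene of the energy-sensing kinase SnRK1, went from 1589 ± 307 to 44.5 ± 14.3, a log2 change of -4.74 ± 0.243. *MCCA*, a subunit gene of methylcrotonyl-CoA carboxylase in leucine degradation, had a log2 change of -4.23 ± 0.252. The other genes among the 12 lowest were *AT1G72060*, *AT2G05540*, *AT5G19120*, *AT1G22890*, *AT2G41250*, *AT1G68440*, *AT3G22060* and *AT4G27450*, with log2 changes between -5.61 and -4.60.

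**Figure D1:**
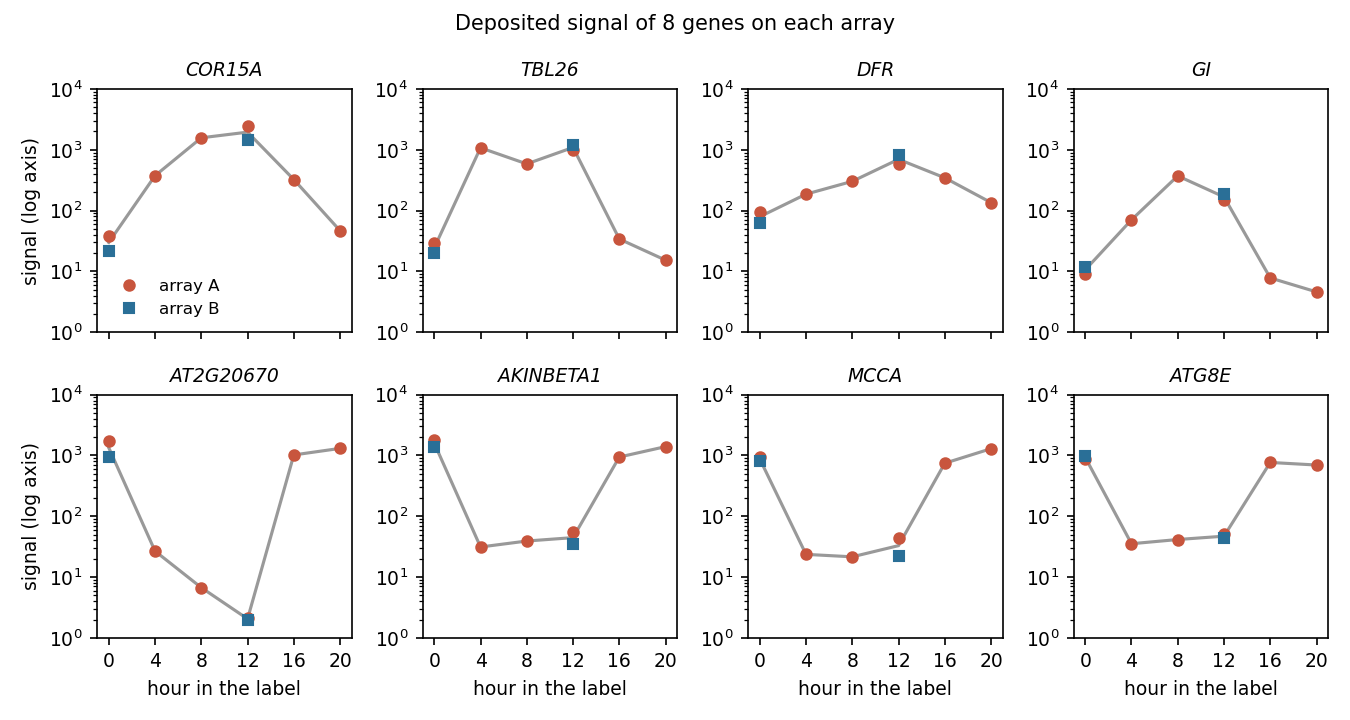
Deposited signal (log axis) of 8 genes against the hour in the label, with a point per array (circles A, squares B) and a line through the mean of each hour. *COR15A*, *TBL26*, *DFR* and *GI* are high by 08h or 12h, while *AT2G20670*, *AKINBETA1*, *MCCA* and *ATG8E* are below 60 at 04h, 08h and 12h and far higher at 16h, 20h and 00h. *DFR* and *ATG8E* come from the gene lists.

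In all, 5528 of 13647 probe sets differed between 12h and 00h (limma adjusted p under 0.05), 2992 of them higher at 12h and 2536 lower, and 3417 differed over 2-fold. The arrays of 12h lay entirely above or below those of 00h for 71% of tested probe sets, where chance gives 33.3%. Over all tested probe sets, the change between the 2 arrays with high hybridisation controls correlated at 0.903 with that between the 2 others. With the array batch as a block all 5528 passed, among 6913. Both hours have an array of either batch, so the block leaves these changes as they are and alters only the spread. That all passed is thus no test of a batch effect. Scaling every array to 1 median, which shifts the median change by 0.134 log2 units, gave 2434 higher and 3056 lower, so the direction of the balance depends on the scaling. Actin 3' over 5' intensity was 3.11 and 3.19 at 12h, and 2.69 and 2.74 at 00h.

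Among the gene lists fixed before the data were examined, genes induced by sugar starvation and darkness fell together at 12h. All 5 tested members of 26 listed were lower, also adjusted over the list alone, with a median log2 change of -4.23 (camera adjusted p = 1.63e-04). With an estimated correlation, which tests on only 2 residual degrees of freedom, camera gave adjusted p = 0.821. The 4 members with the largest statistics were *AKINBETA1*, *MCCA*, *AT3G15450* and *IVD* (isovaleryl-CoA dehydrogenase; -3.06 ± 0.291). Inside the batches the median was -4.01 and -4.45. Of 8 tested autophagy genes, all of the ATG8 family of autophagosome proteins, 6 were lower at 12h over all probe sets and over the list alone, with a median of -1.21 (camera adjusted p = 0.00361; adjusted p = 0.821 with an estimated correlation). *ATG8E* fell from 929.2 ± 84.9 to 47 ± 4.38 (SD, n = 2 arrays each), *ATG8H* had a log2 change of -1.87 ± 0.295, *ATG8F* of -1.77 ± 0.276 and *APG8A* of -1.48 ± 0.268, while 2 of the 8 did not pass.

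Genes of starch metabolism rose, in a mutant that makes little starch. All 3 tested starch synthesis genes of 15 listed were higher at 12h, also over the list alone, with a median of 1.87 (camera adjusted p = 0.012; adjusted p = 0.821 with an estimated correlation). *APL3*, a large subunit gene of ADP-glucose pyrophosphorylase, went from 15.15 ± 1.34 to 283.5 ± 74.1, *SBE2.2*, a branching enzyme gene, rose by 1.87 ± 0.23 log2 units and *APL4* by 1.68 ± 0.229. Both tested starch degradation genes rose, *DPE1*, of the plastidial disproportionating enzyme, by 2.55 ± 0.205 and *PWD*, of phosphoglucan water dikinase, by 2.24 ± 0.211, also over the list alone. *DFR*, of dihydroflavonol reductase and the 1 tested member of the flavonoid list, rose from 79.2 ± 23.6 to 697.6 ± 154. Of 3 cytosolic ribosomal protein genes of the fixed list, 2 were higher over all probe sets and 3 over the list alone (*AT5G02870* 1.41 ± 0.279, *AT2G19730* 1.09 ± 0.273, *AT3G09630* 0.713 ± 0.312), with camera adjusted p = 0.109.

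Few of the tested photosynthesis genes passed the main test, and how many passed depends on how the spread is estimated. None of 3 tested Calvin-Benson cycle genes of 21 listed passed (*RCA* -0.788 ± 0.438, *PRK* -0.416 ± 0.4, *SBPASE* -0.245 ± 0.334), with 0 over the list alone. Of 3 tested light-harvesting genes of 18 listed *LHCB4.2* was lower (-0.842 ± 0.3; limma adjusted p = 0.0463), with 0 over the list alone. Of 3 tested photorespiration genes of 12 listed *AT1G80380*, of glycerate kinase, was lower (-0.746 ± 0.231), also over the list alone. The array batch as a block leaves these changes as they are and raised the calls over all probe sets from 5528 to 6913. With this block *RCA* (limma adjusted p = 0.00343) and *HPR* of photorespiration (0.00988) also passed as lower. *PRK*, *SBPASE*, *LHCB4.1*, *LHCB4.3* and *AT1G11860* did not pass there either. The 4 reference genes did not pass (*PEX4* -0.415 ± 0.218, *AT4G34270* -0.463 ± 0.216, *AT2G28390* 0.0882 ± 0.245, *GAPC2* -0.0514 ± 0.383). Among markers of other cell types and of handling, *FMA* of guard cells (0.112 ± 0.287) and *SWEET11* of the phloem (-0.477 ± 0.308) did not pass. *PYK10*, a root marker, was 285.9 ± 19.9 at 00h and 123.5 ± 4.67 at 12h (limma adjusted p = 0.00182), and *STZ*, induced by touch and wounding, was 140.2 ± 8.98 and 33.9 ± 14.4. The lists of morning clock genes, clock outputs, nitrate assimilation and flower markers had no named probe set, and the 1 named heat shock gene lay below the filter, so they are not analysed here.

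Lists added from gene names gave larger sets. Of 107 cytosolic ribosomal protein genes, 71 were higher and 0 lower at 12h, with a median of 1.04 (camera adjusted p = 5.59e-15; adjusted p = 0.58 with an estimated correlation), and inside the batches the median was 1.01 and 1.04. *AT3G06680* rose from 117.4 ± 9.4 to 750.8 ± 91.6 (SD, n = 2 arrays each) and *AT4G30800* by 2.59 ± 0.243 log2 units. All 7 genes of flavonoid modification, *DFR* and *AT4G14090* among them, were higher, with a median of 2.91 (camera adjusted p = 1.73e-05; adjusted p = 0.91 with an estimated correlation). *UF3GT* rose by 3.51 ± 0.275. A longer sugar starvation list, which holds the 5 genes above, had 15 of 15 members lower, with a median of -3.06 (camera adjusted p = 1.9e-11; adjusted p = 0.91 with an estimated correlation). *AT5G57655*, a xylose isomerase gene, fell from 707.2 ± 2.76 to 36.3 ± 9.76. Knowledge of starvation genes in this plant comes in part from studies of its daily cycle, so the direction of these lists may not be independent evidence.

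**Figure D2:**
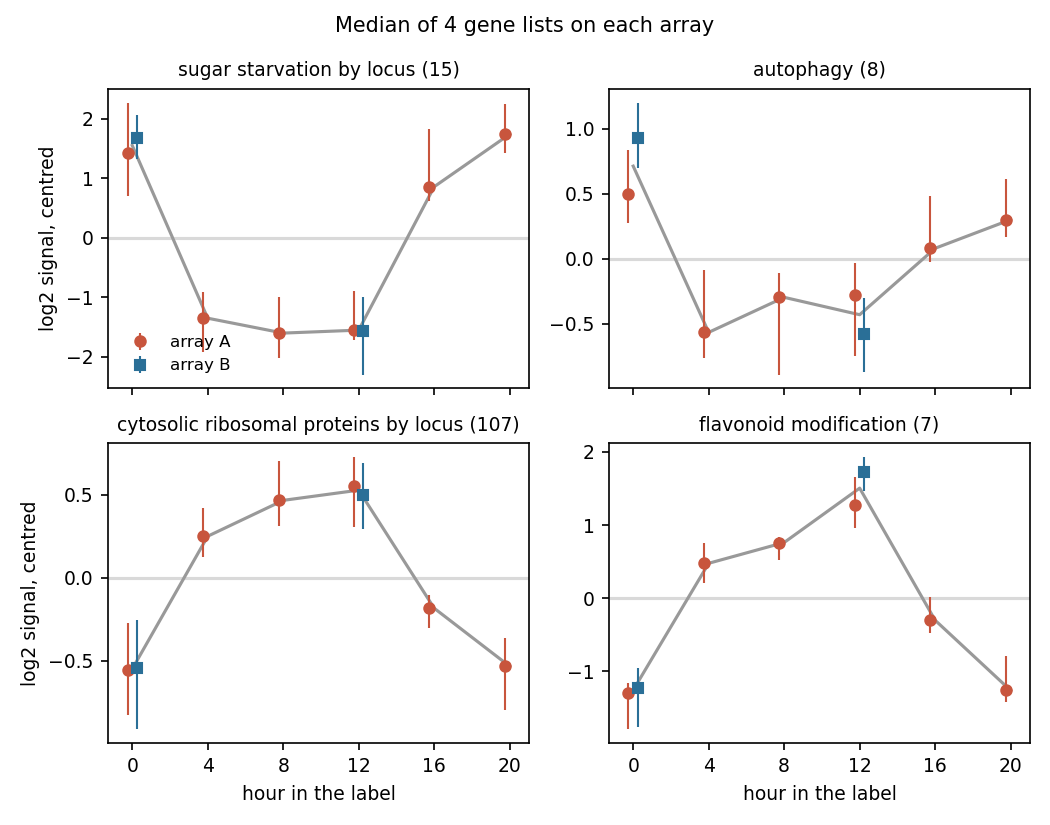
Log2 signal of 4 gene lists against the hour in the label, each gene centred on the mean of its 6 hours, with the median over genes per array (circles A, squares B), bars from the 25th to the 75th percentile and a line through the mean of each hour. The number of genes stands after each name. The sugar starvation list is above 0.8 at 16h, 20h and 00h and below -1.3 at 04h, 08h and 12h, and the ribosomal protein list lies the other way round.

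Over the whole day, 5549 of 13647 probe sets (40.7%) had a 24 h rhythm (limma adjusted p under 0.05), with a median amplitude of 0.714 log2 units and 1445 above 1. A rhythm here means that the fitted 24 h curve passed the test. The hours in the labels do not go beyond a single day and the period was fixed, so whether a pattern recurs was not tested. The largest amplitudes belonged to genes with a late fitted peak, *AT2G20670* (3.98 ± 0.397, SE; peak 20.7 h), *AT3G15450* (3.71 ± 0.55; 20.4 h), *AT5G19120*, *AT3G15630*, *AT1G72060*, *AKINBETA1* (3.24 ± 0.366; 20.4 h), *MCCA* (3.24 ± 0.292; 20.2 h), *AT1G68440* and *AT2G05540*. Only 3 of the 12 peaked before 12h on the fitted curve, *AT1G73600* at 8.47 h, *TBL26* at 8.46 h and *COR15A* at 10.1 h. *GI*, a clock gene with evening expression and the 1 tested member of the fixed clock lists, had an amplitude of 2.22 ± 0.197 and a peak at 8.50 ± 0.318 h, with 372.3 at 08h and 4.6 at 20h. Its amplitude was 1.324 with a pseudocount of 64.

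Peaks of the fitted 24 h curve fell into 2 groups. For a level that is high at 04h, 08h and 12h and low at the other hours, such a curve peaks near 08h, and for the reverse near 20h. The 2 groups may thus restate the split of the arrays described above and are no separate evidence. A peak of this curve need not be the hour with the highest signal, which for *AT3G15450* and *AKINBETA1* was 00h. Of the rhythmic probe sets 2058 (37.1%) peaked nearest 08h, 831 nearest 12h, 1969 (35.5%) nearest 20h and 525 nearest 00h, with 106 nearest 04h and 60 nearest 16h. Of the 107 ribosomal protein genes 85 were rhythmic, 78 of them nearest 08h and 7 nearest 12h. All 5 genes of the fixed sugar starvation list and 14 of 15 of the longer list had their fitted peak nearest 20h, as did 4 of the 6 rhythmic *ATG8* genes. The 3 starch synthesis genes peaked nearest 08h and *DPE1* and *PWD* nearest 12h. With the array batch as a block 6095 probe sets were rhythmic, 5458 of them in both fits and 0 with a peak moved by over 4 h. On only the 6 arrays of the larger batch the count was 3694, over 1.5 times lower.

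The largest step was from 00h to 04h. *AT1G73600* rose by 5.35 ± 0.276 log2 units, from 28.35 ± 1.48 (SD, n = 2 arrays) to 1789 on the single 04h array, *TBL26* by 4.77 ± 0.274 and *AT1G06000* by 3.83 ± 0.326 (2.455 with a pseudocount of 64). *AT3G15450* (-6.20 ± 0.478), *AT5G19120* (-5.50 ± 0.276) and *AT3G15630* (-5.30 ± 0.289) were the lowest. In the fixed lists, 5 of 5 sugar starvation genes were lower (median -4.49; camera adjusted p = 6.92e-06), 5 of 8 autophagy genes were lower and 6 over the list alone (median -1.26; camera adjusted p = 3.26e-04), and 3 of 3 starch synthesis genes were higher (median 1.47; camera adjusted p = 0.0253). Each of these had adjusted p = 0.821 with an estimated correlation. Of the ribosomal protein genes 47 of 107 were higher (median 0.811; camera adjusted p = 1.71e-09; adjusted p = 0.585 with an estimated correlation). Of 13647 probe sets 3690 differed (limma adjusted p under 0.05), 2124 higher and 1566 lower at 04h, and 4668 with the array batch as a block. Without the filter on dim probe sets 2272 differed, and scaling to 1 median, a shift of 0.207, gave 1468 higher and 2074 lower.

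The step from 12h to 16h ran the other way. *AT2G20670* rose by 5.84 ± 0.349 log2 units, from 2.05 ± 0.0707 (SD, n = 2 arrays) to 1019 on the single 16h array, *AT3G15450* by 5.18 ± 0.478 and *AT1G25400* by 4.85 ± 0.279. *TBL26* (-4.46 ± 0.274), *AT1G80130* (-3.13 ± 0.289) and *AT1G06000* (-2.96 ± 0.326) were the lowest. Of the 5 fixed sugar starvation genes 4 were higher and 5 over the list alone (median 4.00; camera adjusted p = 6.92e-06), 2 of 8 autophagy genes were higher and 3 over the list alone (median 0.523; camera adjusted p = 0.0438), and 2 of 3 starch synthesis genes, *APL3* (-2.34 ± 0.302) and *APL4*, were lower and 3 over the list alone (camera adjusted p = 0.00971). The autophagy call ended with a pseudocount of 1 and with the lowest 60% left out. All 3 had adjusted p = 0.821 with an estimated correlation. Of 107 ribosomal protein genes 17 were lower (median -0.672; camera adjusted p = 3.54e-16; adjusted p = 0.58 with an estimated correlation). In all 1526 probe sets differed (limma adjusted p under 0.05), 921 higher and 605 lower. With the array batch as a block the count was 2558, and without the filter 358.

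**Figure D3:**
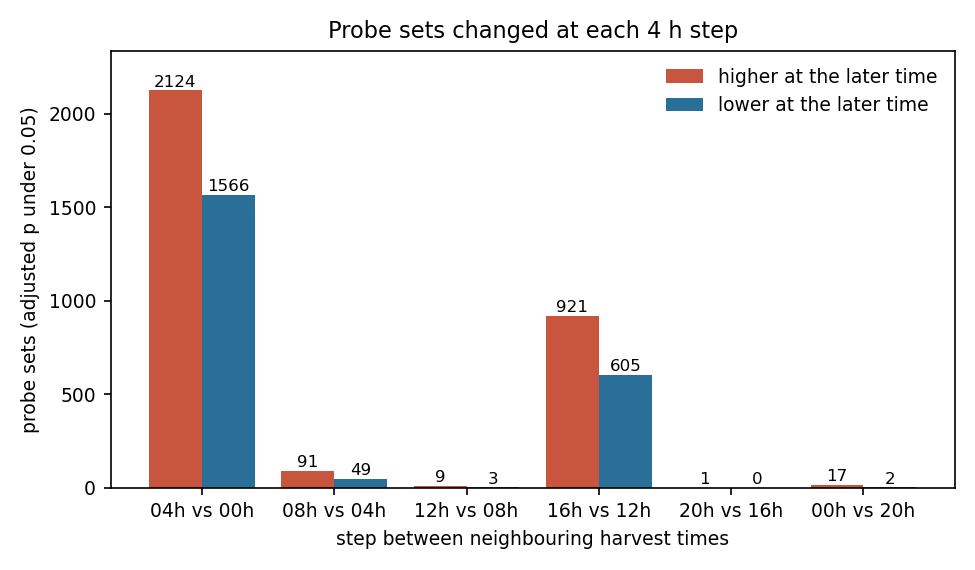
Number of probe sets past an adjusted p of 0.05 in each step between neighbouring hours, with bars for probe sets higher and lower at the later hour, from 13647 tested. The steps from 00h to 04h (2124 and 1566) and from 12h to 16h (921 and 605) exceed the other 4.

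Within the hours between these steps fewer genes changed. From 04h to 08h 140 probe sets differed (91 higher, 49 lower). *AT1G07050* went from 7.9 to 404.4, a log2 change of 4.14 ± 0.367 (SE; limma adjusted p = 8.43e-04), *AT5G62360* rose by 4.09 ± 0.467 and *AT4G32340* by 3.52 ± 0.292. With a pseudocount of 64, *AT1G07050* rose by 2.704 and *AT5G62360* by 2.602. *AT1G65490* (-2.79 ± 0.309), *AT5G15950* (-2.73 ± 0.29), an S-adenosylmethionine decarboxylase gene, and *AT3G21670* (-2.43 ± 0.359), a nitrate transporter gene, were the lowest. From 08h to 12h 12 differed (9 higher, 3 lower), with *AT3G28270* (3.56 ± 0.305), *AT2G23910* (2.26 ± 0.288) and *AT1G65490* (1.92 ± 0.268) higher and *AT5G35970* (-2.11 ± 0.277) lower. From 20h to 00h 19 differed (17 higher, 2 lower), with *AT1G55960* (2.50 ± 0.323) and *AT2G41250* (1.86 ± 0.267) higher and *AT2G03310* (-2.09 ± 0.295) lower. The call of *AT2G03310* ended with a pseudocount of 64 (-1.138). Those of *AT2G23910*, *AT1G65490* (08h to 12h), *AT5G35970* and *AT2G41250* ended with a pseudocount of 1, the last 3 of these also without the intensity trend, and that of *AT1G65490* with 64 too. Without the filter, every call of a gene named in these steps ended. From 16h to 20h 1 probe set differed, which has no gene in the table and was chosen after its values were seen. It rose from 7.7 to 337.8, a log2 change of 3.90 ± 0.325 (SE; limma adjusted p = 0.00329).

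In 5 cases a fixed list passed in these steps while 0 of its members did, over all probe sets or over the list alone. From 04h to 08h photorespiration genes were lower (median -0.459; camera adjusted p = 0.0479) and starch synthesis genes higher (0.514; 0.0401). From 08h to 12h photorespiration genes were higher (0.639; 0.00827), from 16h to 20h sugar starvation genes (0.589; 0.00309) and from 20h to 00h autophagy genes (0.397; 0.00409). All had adjusted p = 0.821 with an estimated correlation.

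The 4 counts of these steps depend on how the spread between arrays is estimated. The steps from 04h to 08h and from 16h to 20h use no array of 00h or 12h. Their log2 changes were the same with the array batch as a block (SD 0.471 and 0.382 in both fits). Their counts thus moved only through the spread, which has 1 residual degree of freedom with the block. With the array batch as a block they were 460, 148, 96 and 109 in the order given, with 229 higher and 231 lower, 66 and 82, 46 and 50, and 31 and 78, so the excess of higher probe sets was not kept. Without the filter each was 0. With it, 1085, 899, 859 and 714 probe sets had an unadjusted p under 0.05. A share of 0.05 of the 13647 tested would do so on average without any change, so these are not counts of changed probe sets. Leaving out 00h A gave 355, 131, 108 and 85, without 00h B 353, 133, 83 and 87, without 12h A 255, 43, 48 and 44, and without 12h B 257, 41, 46 and 44.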

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

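The array batch block and the fit on the 6 arrays of the larger batch were chosen after seeing the data. The cause of the changes below was not tested. The count for 12h vs 00h stayed between 4214 and 6913 under every alternative run, and the rhythm count between 4145 and 6095 except on only the 6 arrays of the larger batch, where it was 3694 and which has fewer samples. With each array left out in turn, the rhythm count ran from 4501 to 5479. The contrasts were run without 1 array only for the 4 arrays of 00h and 12h, and their counts ran from 4631 to 5071 for 12h vs 00h, 3218 to 4243 for 04h vs 00h, 255 to 355 for 08h vs 04h, 41 to 133 for 12h vs 08h, 1456 to 2134 for 16h vs 12h, 44 to 87 for 20h vs 16h and 46 to 108 for 00h vs 20h. An hour left with 1 array was assumed to vary like the others.

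With the replicate letter as a block (replicate block), 08h vs 04h gave 460, 12h vs 08h 186, 16h vs 12h 2789, 20h vs 16h 109 and 00h vs 20h 141. The A minus B differences of 00h and 12h correlated at 0.297 over probe sets, but there are only 2 such pairs. At 00h and 12h the letters coincide with the array batches, so the letter carries the batch there and both blocks gave 6913 for 12h vs 00h, while the labels name nothing shared by arrays of 1 letter. With the array batch block the counts were 460, 148, 2558, 109 and 96. Without the filter they were 0, 0, 358, 0 and 0, and 2272 for 04h vs 00h. A pseudocount of 1 gave 4 for 12h vs 08h and 11 for 00h vs 20h, a pseudocount of 64 gave 20 for 12h vs 08h, no intensity trend gave 5 for 12h vs 08h, and quantile normalization gave 4 for 20h vs 16h. Of 56 pairs of fixed list and contrast, 14 passed, against 8 with a pseudocount of 1, 8 with the lowest 60% left out, 0 with an estimated correlation and 0 with fry. No named value reversed, nor did any list that passed in 12h vs 00h, 04h vs 00h or 16h vs 12h. Medians of lists that did not pass changed sign in places, and list results of the 4 small steps were compared only as the count of passing pairs. Of 62 named values 4 no longer passed with a pseudocount of 1, 2 with 64, 13 without the filter and 3 without the trend, all of them in the 3 small steps that name genes, and 0 under the blocks, the scalings or without 1 array of 00h or 12h. Without 04h, 08h, 16h or 20h only the 13 amplitudes were run, and 0 ended. The size of 8 of the 62 moved by over 1.5 times, 8 with a pseudocount of 64 and 2 with 1.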

Other observations

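The tests for batch and scaling of the 2 large steps below were chosen only after the result was seen, and the rule for reading the test of the 04h array was changed after its result was seen, from a call of a defect to an open one. Genes of branched-chain amino acid and lysine degradation fell at 12h against 00h, with 7 of 11 lower and a median log2 change of -1.19 (camera adjusted p = 0.00193; adjusted p = 0.91 with an estimated correlation). The list shares 5 genes with the longer starvation list, in which 15 of 15 were lower. Most of the 7 lower genes are thus those 5, and the fall is not separate from that of the starvation genes. Beside *MCCA* and *IVD*, *AT4G33150*, of lysine degradation, had a log2 change of -2.20 ± 0.258 (SE) and *AT2G26800*, a hydroxymethylglutaryl-CoA lyase gene of leucine degradation, of -2.01 ± 0.224. RNA polymerase subunit genes rose, 6 of 10 higher (median 0.984; camera adjusted p = 0.0123; adjusted p = 0.91 with an estimated correlation), with *NRPA2* of RNA polymerase I at 1.66 ± 0.23 and *NRPC2* of RNA polymerase III at 1.51 ± 0.236. Of 5 tested endoglucanase genes of family GH9, 4 rose (median 1.65; camera adjusted p = 0.0403; adjusted p = 0.918 with an estimated correlation), and *GH9C2* went from 27.1 ± 2.26 to 465 ± 137. The GH9 call ended with either other pseudocount and with the lowest 60% left out, and the RNA polymerase call with the lowest 60% left out.

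Sugar transporter genes of the SWEET family went both ways. *SWEET13* was 11.5 ± 2.26 at 00h (SD, n = 2 arrays) and 177.7 at 04h, a log2 change of 2.82 ± 0.279 (SE), and *SWEET17* rose by 2.15 ± 0.256, while *SWEET2* was lower at 12h (-2.93 ± 0.361). Of 8 tetrapyrrole synthesis genes 4 were higher at 12h, and *PORB*, a protochlorophyllide oxidoreductase gene, went from 373.6 at 04h to 2183 at 08h, a log2 change of 2.50 ± 0.332. Of 8 cold and dehydration genes 3 were higher at 08h than at 04h (*COR15B* 3.44 ± 0.309, *COR15A* 2.02 ± 0.401 and *COR27*, whose 04h value is weighed below), with a list median of 1.38 (camera adjusted p = 2.88e-09; adjusted p = 0.91 with an estimated correlation). At 12h against 00h 3 of the 8 were higher, with a median of 0.187 (camera adjusted p = 0.473). Of 8 genes tied to the clock by locus 3 were higher at 08h than at 04h, *GI* (2.17 ± 0.333), *COR27* and *AT4G33980* (camera adjusted p = 0.00872; fry adjusted p = 0.0238; adjusted p = 0.91 with an estimated correlation). These values and those that follow rest in part on the 04h lows of *COR27* and *AT4G33980* weighed below. At 04h against 00h *GI* was higher and *COR27* and *MYBC1* (-1.06 ± 0.287) lower (camera adjusted p = 0.516; fry adjusted p = 0.0391), and 3 of the 8 were rhythmic. Genes of the plastid genome changed little, with 6 of 33 photosynthesis genes higher and 0 lower at 12h against 00h (median 0.0955). Over all tested probe sets 2992 of 13647 were higher.

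The change from 00h to 04h and that from 12h to 16h, which share no array, mirrored each other, with a correlation of -0.73 over probe sets, which are not independent replicates. Of 1162 probe sets changed in both steps 1154 went in opposite directions, 492 higher then lower where independent lists would share 94.2, and 662 lower then higher where they would share 106. The steps between neighbouring hours close the day, so over all of them the log2 changes of a probe set cancel. With the other steps small, opposite directions in these steps largely follow from this arithmetic. The shares of independent lists are therefore no fitting reference, and the mirroring is no separate evidence. No other explanation of it was tested.

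These 2 steps changed many probe sets and the other 4 few. Neither the array batch nor the scaling accounts for this contrast in size. Inside the larger batch the smaller SD of log2 changes of the 2 steps was 1.638 times the largest SD of the other 4, and with all arrays at 1 median the smaller of the 2 counts was 10.8 times the largest of the others. A change of state of the rosette between light and dark, whose hours the labels used here do not give, was not tested.

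Brightness of the probe sets and the array batch were weighed for the rise of the 107 ribosomal protein genes at 12h. Their median lay above all of 10000 random lists matched on mean signal (percentile 100), so brightness does not account for the rise. The smaller of the 2 medians inside the batches was 1.01, so the rise was present in both. Both hours have an array of either batch, so a batch shift common to both hours cancels by design. The medians are therefore hardly a test of the batch. A hypothesis is that ribosome synthesis follows the supply of sugar, with the starvation genes moving the other way, but no sugar level or wild type is analysed here and it was not tested.

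*COR27* and its relative *AT4G33980*, which were chosen after their values were seen, lay at the floor on the 04h array, at 0.8 and 0.4, while *COR27* was 197.2 ± 28.8 at 00h (SD, n = 2 arrays) and 168.4 at 08h and *AT4G33980* was 22.45 ± 7.85 at 00h, 118.5 at 08h, 43.35 ± 29.5 at 12h and 191.6 at 16h, so its low is less particular to 04h. Neither passed the test for a 24 h curve. A defect of the 04h array might give such lows, and there 2 probe sets, *COR27* and 1 without a gene in the table, lay at least 3 log2 units below every other array, against 0 on each of the other arrays. By 2 log2 units it was 9 probe sets there, *COR27* but not *AT4G33980* among them, against 1 at 08h and 0 on the other 6 arrays. With only 1 array at 04h the array and the hour coincide, so a defect and a short trough at that hour cannot be told apart.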
